A study of Rattus norvegicus with 12 samples.

How the data were processed

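Total RNA from the uteri of 12 ovariectomized Lewis rats, 3 in each of 4 treatment groups, was labelled as biotinylated cRNA and hybridised to Affymetrix arrays, 1 array per rat, per the labels' protocols. The deposited values are intensity summaries per probe set on a linear scale, made with Affymetrix Expression Console and its PLIER algorithm per the submitters' processing notes, which give no versions or settings. A genome build, an annotation and a between-array normalization are not given in the sources used here. The values are positive and run from 1.16e-04 to 15672. The medians and spreads of the arrays differ, so the deposited values were not all forced to a common distribution. Vehicle rat 1 had the widest spread, with an interquartile range of 2.70 on the log2 scale against 1.87 to 2.35 on the other arrays.

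The table holds 29214 probe sets. Names came from the annotation of the array platform, in which 15310 probe sets have 1 gene symbol, 323 have several and 13581 have no listed gene. Symbols were checked against RefSeq genes of assembly GRCr8, used for names only: 15279 probe sets matched, 31 symbols had no match, and 0 symbols were changed. Probe sets with several symbols or none were left out of the gene tests. For the 527 genes with several probe sets, the probe set with the highest mean over all arrays was kept, which left 14506 genes.

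Intensities were transformed as log2(intensity + 16). The 30% of genes with the lowest mean over all 12 arrays were left out, at a limit of 6.44, and 10154 genes were tested. All 12 arrays entered a limma model with 1 mean per group (lmFit and eBayes, trend and robust options off), because 3 rats against 3 alone leave 4 residual degrees of freedom and the 4 groups together leave 8. The prior degrees of freedom were 8.92. The contrasts were E2 minus vehicle, 3-MC minus vehicle, E2+3-MC minus vehicle, E2+3-MC minus E2, E2+3-MC minus 3-MC, and the interaction, (E2+3-MC minus E2) minus (3-MC minus vehicle). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, two-sided, and a gene was called at an adjusted p under 0.05. A log2 difference on this scale understates the change of dim genes.

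The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names, for each comparison, the marker genes Cyp1a1, Cyp1b1, Ahrr, Tiparp, Nqo1, C3, Pgr, Clu, S100g, Igf1, Esr1, Ahr, Mki67 and Pcna whatever their result. It then names the 5 largest rises and 5 largest falls among called genes whose 3 rats per group do not overlap. From each gene list it names up to 4 called members with the largest changes, or up to 2 members by value only where none was called. Cuzd1 between 3-MC and vehicle and Dnajc14 between E2+3-MC and E2 fall outside this rule and were chosen after their values were seen.

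The 37 gene lists, with 1002 genes of which 855 matched a measured gene, cover pathways that fit estradiol and AhR ligands and markers of cell types that a uterus or its surroundings can hold. A list with at least 5 tested members was tested with limma's camera at a preset correlation between genes of 0.01, with camera at a correlation estimated from the residuals, and with fry, each adjusted by the Benjamini-Hochberg method over the 35 lists that had enough members. Camera compares a list's genes with all other genes tested, so its direction is relative to them; fry asks whether the members move, on balance, in 1 direction. The numbers of members called over all genes tested and adjusted over the list alone are given beside these tests.

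The relation between comparisons was described across genes by Pearson and Spearman correlation, covariance and the overlap of calls, beside 100 simulations of unchanged groups. The fitting and list steps were tested on simulated data made from the real means and spreads, with noise drawn independently for each gene. For the gene tests, 100 genes were changed by a log2 difference of 1 and 100 by 2 among 10154. For E2 minus vehicle, 61 and 99 of these were called; for 3-MC minus vehicle 59 and 100; for E2+3-MC minus vehicle 57 and 99; for E2+3-MC minus E2 63 and 97; for E2+3-MC minus 3-MC 56 and 98; and for the interaction 28 and 86. A simulated list of 30 genes shifted by 0.5 had a camera adjusted p of 2.04e-23, and of 1.82e-04 with an estimated correlation. Members of real lists vary together, with a mean correlation of up to 0.856 on the deposited scale (ER protein folding). After quantile normalization it was 0.277 for that list and at most 0.789 (adipocytes). Part of this correlation thus went with the scale of the arrays. Tests with an estimated correlation are on the deposited scale unless stated otherwise. Because members vary together, the simulations can overstate the sensitivity of the tests, also where fewer genes change than were changed in them.

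The alternatives tried were quantile normalization, median centring, another offset in the log2 transform, no dim filter and a stricter filter at 50%, the mean of a gene's probe sets, every probe set in place of 1 per gene, only the groups compared, limma's trend and robust options, estimated array weights, stricter thresholds, the replicate number as a block, and each rat left out in turn. Combinations of quantile normalization with the block, without vehicle rat 1, without E2+3-MC rat 2 and without both were chosen after seeing the data. Differences between groups in the mean of a list's members per rat, with and without these 2 rats, were also chosen after seeing the data. Array weights were estimated gene by gene, since the iterative REML method did not converge on the deposited values. All computations used R 4.3.3 with limma 3.58.1.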

Results

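Gene expression was measured in the uteri of ovariectomized young adult Lewis rats, animals whose ovaries, the main source of estrogens, have been removed. Rats received vehicle, estradiol (E2) at 4 µg/kg per day, 3-methylcholanthrene (3-MC) at 15 mg/kg per day, or both compounds (E2+3-MC). 3-MC is a polycyclic aromatic hydrocarbon that binds the aryl hydrocarbon receptor (AhR), a transcription factor that switches on enzymes of xenobiotic metabolism. Dosing lasted 3 days and the tissue was collected 24 hours later. Each of the 4 groups held 3 rats, with 1 Affymetrix array per rat and 12 arrays in all. The median intensity of an array ranged from 86.3 in E2 rat 3 to 124 in 3-MC rat 1. Vehicle rat 1 stood apart in its spread, with an interquartile range of 2.70 on the log2 scale against 1.87 to 2.35 on the other 11 arrays. The number of arrays limits the precision: the median standard error (SE) of a difference between groups was 0.22 on the log2 scale. Values below are log2 differences ± SE between groups of 3 rats unless stated otherwise, and "called" means an adjusted p under 0.05 in limma over 10154 genes.

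Genes known to follow estradiol separated the groups by treatment. C3, which encodes the central complement protein and is a classic estradiol-induced gene of rat uterine epithelium, had a mean log2 level of 5.86 ± 0.33 (SD, n = 3) with vehicle and 12.55 ± 0.16 with E2. Its level was 7.01 ± 0.49 with 3-MC and 12.29 ± 0.37 with both compounds. S100g, the calcium-binding protein calbindin-D9k, rose by 4.93 ± 0.23 from vehicle to E2 and by 4.93 ± 0.23 from vehicle to E2+3-MC. Clu, the chaperone clusterin, fell by 3.41 ± 0.23 and by 2.97 ± 0.23 in the same comparisons. Igf1, a growth factor made in uterine stroma, rose by 1.33 ± 0.32 with E2 (adjusted p = 0.00799). The progesterone receptor gene Pgr rose by 0.68 ± 0.22 with E2 (adjusted p = 0.0363). The estrogen receptor gene Esr1 was lower by an uncalled -0.46 ± 0.25 (adjusted p = 0.209), a difference that was called at -0.64 after quantile normalization. The proliferation gene Pcna differed by 0.39 ± 0.23 with E2 (adjusted p = 0.271) and rose by 0.80 ± 0.23 with both compounds (adjusted p = 0.0453).

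Genes known to follow AhR ligands were not called between 3-MC and vehicle. Cyp1a1, the standard AhR-induced monooxygenase, had mean log2 levels of 5.32 with vehicle, 5.12 with E2, 5.40 with 3-MC and 5.37 with both. All of these lie under 6.44, the limit of the dim genes that were left out of the tests. The 3-MC minus vehicle difference was 0.08 ± 0.19 for Cyp1a1, 0.08 ± 0.15 for Cyp1b1 and 0.04 ± 0.15 for the AhR repressor gene Ahrr, each in the dim range. In the same comparison Nqo1, a quinone reductase, differed by -0.23 ± 0.21 and Ahr itself by -0.01 ± 0.21 (adjusted p = 1.00 for both). With E2 present Ahrr did differ in value: its intensities were 46.1, 51.2 and 43.6 in the rats given E2+3-MC and 31.8, 24.1 and 23.2 in those given E2, without overlap. The log2 difference of 0.58 ± 0.15 (0.33 after quantile normalization) was outside the test as dim. Of all genes tested, 17.9% did not overlap between E2+3-MC and E2 either, against 10% by chance. This share is on the deposited scale, where the array medians of these groups did not overlap. Ahrr intensities were 53.9, 66.4 and 57.8 with vehicle. Aldh3a1, an AhR-induced aldehyde dehydrogenase, was an uncalled 0.62 ± 0.22 higher with E2+3-MC than with E2 (adjusted p = 0.503; 0.36 after quantile normalization). In that comparison 2 other AhR target genes were lower and also uncalled, Scin by -0.80 ± 0.29 (-0.91 after quantile normalization) and Nqo1 by -0.14 ± 0.21 (-0.39). Tiparp and Mki67, also chosen as markers, had no probe set with a single gene symbol.

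**Figure D1:**
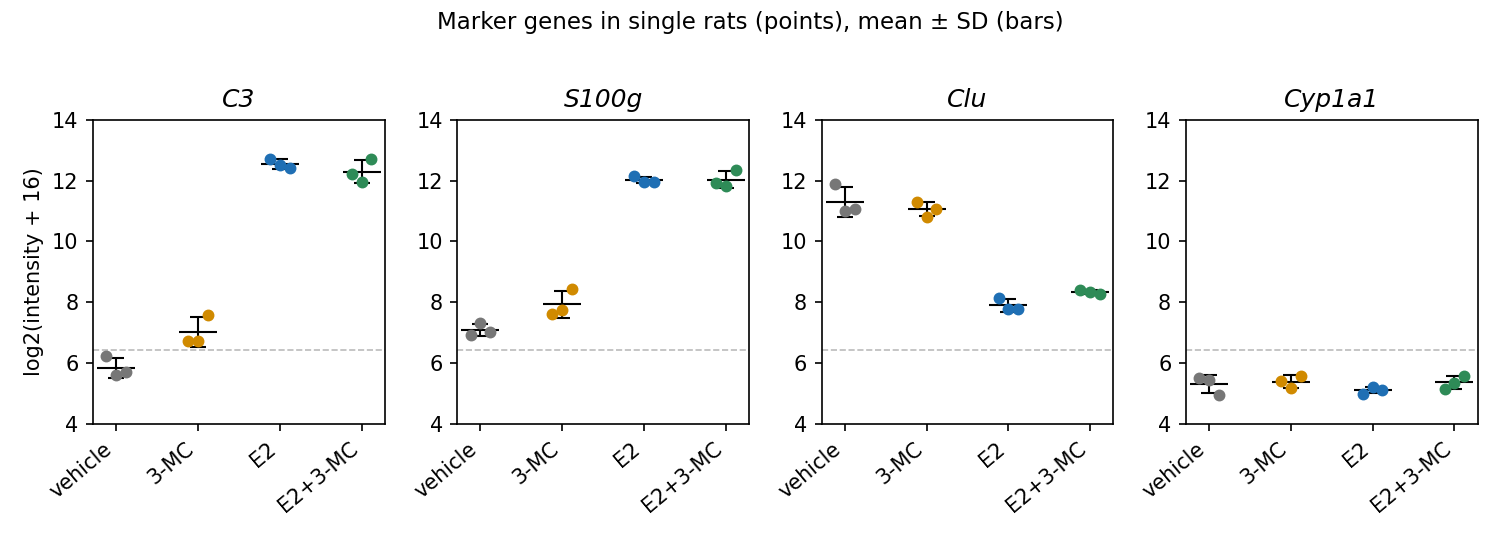
Log2(intensity + 16) of C3, S100g, Clu and Cyp1a1 in each of the 12 rats by treatment group, with the mean and SD of 3 rats; the dashed line marks the dim limit of 6.44. C3 and S100g lie higher and Clu lower in both groups given E2, while Cyp1a1 stays under the dashed line in all groups.

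The comparison of E2 with vehicle asks how the ovariectomized uterus responds to estradiol. The largest rises were in Reg3g, Prss32, Mmp7, Cuzd1 and C3. Reg3g, an antibacterial lectin, rose 192-fold (7.59 ± 0.60), the serine protease gene Prss32 rose 154-fold (7.26 ± 0.26), and the matrix metalloproteinase gene Mmp7 rose 139-fold (7.11 ± 0.28). Cuzd1, a gene of estrogen-responsive uterine epithelium, rose 127-fold (6.99 ± 0.25) and C3 rose 103-fold (6.69 ± 0.26). The largest falls were in the acyl-CoA thioesterase gene Them5 (-5.70 ± 0.29), the glutathione transferase gene Gstm7 (-4.77 ± 0.40) and Gulo, the last enzyme of vitamin C synthesis (-4.32 ± 0.28). Cadps, a regulator of dense-core vesicle release, fell by 3.89 ± 0.29, and the fatty acid desaturase gene Scd fell too (-3.64 ± 0.88). The vehicle levels of Reg3g, Prss32, Mmp7, Cuzd1 and C3 (5.58, 5.03, 5.34, 5.40 and 5.86) lay under the dim limit of 6.44, so the sizes and order of these folds are uncertain. Folds are on the scale of log2(intensity + 16), which understates the change of dim genes.

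Lists of interferon response, estrogen-induced, epithelial, cholesterol synthesis, protein folding and mitosis genes had more members that rose than fell with E2. Of 29 interferon response genes tested, 19 rose and 10 did not pass (25 higher and 1 lower when adjusted over the list alone), among them the antiviral genes Mx1 (2.48), Isg15 (2.42) and Ifit3 (2.08) and the regulator Irf7 (1.83). The list's camera adjusted p was 2.01e-12, and adjusted p = 0.676 with an estimated correlation. Of 26 estrogen-induced uterine genes, 13 rose and 3 fell (16 and 3 when adjusted over the list alone), with Lcn2, an iron-scavenging lipocalin, up by 3.62 and Clca1 up by 3.22 (camera adjusted p = 2.21e-09; adjusted p = 0.676 with an estimated correlation). Of 29 genes of luminal and glandular epithelium, 14 rose and 2 fell (19 and 3 when adjusted over the list alone), with the transcription factor Elf3 up by 3.53 and the keratins Krt8, Krt19 and Krt7 up by 2.93, 2.65 and 2.03 (camera adjusted p = 7.95e-08; adjusted p = 0.676 with an estimated correlation). Of 18 cholesterol synthesis genes, 8 rose (10 when adjusted over the list alone), with the isomerase Idi1 up by 2.90 and the demethylase Cyp51 by 2.03 (camera adjusted p = 5.32e-07; adjusted p = 0.676 with an estimated correlation). Of 31 genes of ER protein folding, 10 rose and 1 fell, the same counts as when adjusted over the list alone, with the disulfide isomerase Pdia6 up by 1.40 (camera adjusted p = 1.16e-04; adjusted p = 0.739 with an estimated correlation). Of 23 mitosis genes, only 3 rose (3 when adjusted over the list alone): the mitotic kinase gene Cdk1 (2.12), Kif23 (1.77) and Prc1 (1.28), genes of cell division (camera adjusted p = 0.00974, and 0.154 without vehicle rat 1; adjusted p = 0.775 with an estimated correlation).

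Immune lists differed in how many members were called and in which direction. Of 19 macrophage markers, 11 rose (13 when adjusted over the list alone), with Cd86 up by 1.73 and the scavenger receptor gene Cd68 by 1.59 (camera adjusted p = 8.36e-08; adjusted p = 0.676 with an estimated correlation). Of 19 antigen presentation genes, 4 rose (5 when adjusted over the list alone), namely the protease Ctss (1.34) and the immunoproteasome subunits Psmb10 (1.09), Psmb9 (1.03) and Psmb8 (1.01) (camera adjusted p = 2.42e-05; adjusted p = 0.676 with an estimated correlation). Of 17 complement genes, 7 rose and 1, Clu, fell (8 and 1 when adjusted over the list alone), with Cfi up by 3.26 and Cd55 by 2.88, both of which limit complement activation (camera adjusted p = 2.69e-04; adjusted p = 0.676 with an estimated correlation). Of 30 chemokine and cytokine genes, 11 rose and 5 fell (11 and 8 when adjusted over the list alone), with the eosinophil attractant Ccl11 up by 4.89, Cxcl6 by 4.55 and Cxcl17 by 3.47 (camera adjusted p = 0.00713, and 0.0612 after quantile normalization; adjusted p = 0.706 with an estimated correlation). Of 6 neutrophil markers, 3 rose and 2 fell (camera adjusted p = 0.101), with S100a9 up by 2.73 and Mpo down by 1.17 (a log2 difference of -1.17). None of 6 markers of T, NK and B cells was called by limma (camera adjusted p = 0.738), with Gzmb at -0.57 and Cd27 at -0.49. Eosinophil and mast cell markers had 3 tested genes each, too few for a list test: the eosinophil genes Alox15 and Siglec5 differed by an uncalled -0.55 and -0.28, while among mast cell genes Kit rose by 1.83, Cpa3 fell by 1.11 and Gata2 fell by 0.71.

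Lists of endothelial, Wnt pathway, mesothelial, adipocyte, blood and steroid receptor genes had more members that fell than rose with E2. Of 20 endothelial markers, 11 fell (14 lower and 1 higher when adjusted over the list alone), with the junction genes Cldn5 and Cdh5 falling by 1.12 and 1.02 (camera adjusted p = 1.16e-04; adjusted p = 0.676 with an estimated correlation). Of 33 Wnt pathway genes, 13 fell (15 lower and 1 higher when adjusted over the list alone), both the ligand Wnt2 (-1.55) and the Wnt-responsive receptor Lgr5 (-1.63) and the secreted Wnt inhibitors Wif1 (-3.51) and Sfrp1 (-1.54) (camera adjusted p = 5.82e-04; adjusted p = 0.706 with an estimated correlation). Of 5 mesothelial markers, 3 fell (4 when adjusted over the list alone), with Gpm6a at -1.67 and Msln at -1.44 (camera adjusted p = 0.00351; adjusted p = 0.676 with an estimated correlation). Of 12 adipocyte markers, 8 fell (9 when adjusted over the list alone), with the fatty acid binding protein gene Fabp4 at -3.59 ± 1.12 and the lipase gene Lpl at -2.44 ± 0.55 (camera adjusted p = 0.00383, and 0.0782 without E2 rat 1; adjusted p = 0.706 with an estimated correlation). These markers varied widely between rats of 1 group, with an SD of 1.38 for Fabp4 among vehicle rats. Of 6 blood genes, 3 fell, with the globin genes Hbb and Hbb-b1 at -2.24 and -2.06 (camera adjusted p = 0.0408, and 0.0887 after quantile normalization; adjusted p = 0.676 with an estimated correlation). Of 19 steroid receptor and cofactor genes, 1 rose and 5 fell, the same counts as when adjusted over the list alone, with Arnt2 at -2.64 and the mineralocorticoid receptor gene Nr3c2 at -1.28 (camera adjusted p = 0.042, and 0.113 without vehicle rat 1; adjusted p = 0.775 with an estimated correlation).

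Other lists had called members in both directions or few of them, and their list tests did not pass. Of 22 water and ion transport genes, 6 rose and 5 fell (camera adjusted p = 0.0717), with the chloride channel Cftr up by 4.49, the anion exchanger Slc26a4 up by 2.12 and the carbonic anhydrase Car2 at -1.83. Of 40 extracellular matrix genes, 5 rose and 4 fell (camera adjusted p = 0.0954), with the protease inhibitor Timp1 up by 2.80, Efemp1 at -2.33 and Postn at -1.78. Of 23 immediate early genes, 5 rose and 1 fell (camera adjusted p = 0.0717), with Fos up by 2.57 and Klf4 by 1.61. Of 26 antioxidant genes, 7 rose and 4 fell (camera adjusted p = 0.197), with Sod2 up by 1.65 and Gstm1 at -2.73. Of 10 AhR target genes, 3 rose and 1 fell (camera adjusted p = 0.212): the actin-severing gene Scin (2.16), Xdh (1.60) and Nqo1 (0.62) rose and Gsta1 (-0.95) fell. In the insulin-like growth factor axis 2 of 17 genes rose and 5 fell (camera adjusted p = 0.147), with Igfbp2 up by 1.91 and Igfbp3 at -1.40. In the EGF receptor axis 3 of 12 genes rose and 2 fell (camera adjusted p = 0.149), with the ligand Btc up by 2.32. Of 23 smooth muscle genes of the myometrium, 2 rose and 1 fell (camera adjusted p = 0.0717), with Des up by 1.12, Actg2 up by 1.08 and Pln at -1.07.

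In the remaining lists the camera test was farther from the threshold. For 11 genes of cornified or stratified epithelium, 4 rose and 3 fell (adjusted p = 0.356), with the desmosome gene Dsc2 up by 3.41; the list median was -0.08, the mean 0.38 and the test upward. For 15 progesterone-responsive genes, 3 rose and 1 fell (adjusted p = 0.873), with the cortisol-inactivating enzyme Hsd11b2 up by 3.16; the median was -0.23, the mean 0.12 and the test upward. For 13 genes of steroid and estrogen metabolism, 2 rose and 3 fell (adjusted p = 0.774), with the sulfotransferase Sult1a1 at -1.99; the median was -0.09, the mean 0.01 and the test downward. For 36 ribosome biogenesis genes, Tsr1 alone rose, by 0.62 (adjusted p = 0.774), with a median of -0.04, a mean of -0.02 and an upward test. In 29 DNA replication genes, Cdc6 rose by 2.22 and Rrm2 by 1.64 (adjusted p = 0.774), with an upward camera test and a downward fry test. Endometrial stroma had 1 of 19 genes higher and 2 lower (adjusted p = 0.380), with the peptidase Mme up by 1.60 and Tcf21 at -1.24. Skeletal muscle had 1 of 7 genes higher and 1 lower (adjusted p = 0.885), with Acta1 up by 2.20 and Tnni2 at -1.27. Oviduct and ciliated epithelium had 2 of 5 genes lower (adjusted p = 0.2002), with Tekt1 at -0.98, and peripheral nerve 2 of 8 lower (adjusted p = 0.0982), with Gap43 at -1.23.

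In limma, 1842 of the 10154 genes were called between E2 and vehicle, 883 higher and 959 lower, and 851 of them changed at least 2-fold. In 1730 of the called genes the 3 E2 rats did not overlap the 3 vehicle rats; over all genes tested this share was 27.2%, where chance gives 10%. The number depended on the scale of the arrays and on single rats: it was 3901 after quantile normalization (1928 higher, 1973 lower), 2336 after median centring (1535 higher, 801 lower), 3541 without vehicle rat 1 (2412 higher, 1129 lower), 1151 without E2 rat 2 (704 higher, 447 lower) and 986 without E2 rat 3 (572 higher, 414 lower). The balance of directions also moved without E2 rat 1 (548 higher, 1227 lower), vehicle rat 2 (606 higher, 833 lower) or vehicle rat 3 (619 higher, 1346 lower). No list call on the deposited scale held with an estimated correlation between genes, in this or any other comparison.

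The comparison of 3-MC with vehicle asks what 3-MC does without estradiol. No gene passed the test, so the following are values only. C3 differed by 1.15 ± 0.26, S100g by 0.85 ± 0.23 and Mmp7 by 0.94 ± 0.28, with all 3 rats given 3-MC above all 3 vehicle rats for each of these genes. Mmp7 lay under the dim limit of 6.44 in both groups (5.34 and 6.28) and C3 did so with vehicle (5.86), so the sizes of their differences are uncertain. The globin genes Hbb and Hbb-b1 differed by -1.13 ± 0.44 and -1.13 ± 0.36. The adipocyte genes Fabp4 and Adipoq differed by -2.33 ± 1.12 and -1.79 ± 0.73, and the Schwann cell gene S100b, also known from fat, by -1.86 ± 0.73. All of these had an adjusted p of 1.00.

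As whole lists, adipocyte markers were lower in 3-MC than in vehicle relative to other genes, with a median of -0.87 over 12 genes (camera adjusted p = 1.29e-08; adjusted p = 0.834 with an estimated correlation). Vehicle rat 1 stood apart, with a mean over these genes of 2.22 against -0.18 and 0.08 in the other vehicle rats and -1.02, -0.62 and 0.69 with 3-MC, and without it the difference of these means went from -1.02 to -0.27. Endothelium (median -0.21), luminal and glandular epithelium (-0.18) and cholesterol synthesis (-0.22) were also lower (camera adjusted p = 0.00735, 0.0159 and 0.0284; adjusted p = 0.929 with an estimated correlation for each). These 4 lists were also called after quantile normalization, but without vehicle rat 1 endothelium, epithelium and cholesterol synthesis were not (adjusted p = 0.172 each), and their mean differences on the deposited scale turned from -0.19, -0.17 and -0.19 to 0.07, 0.10 and 0.09; after quantile normalization they went from -0.13, -0.12 and -0.18 to -0.08, -0.03 and -0.06. Epithelium was also lost without vehicle rat 3 (0.0619) or 3-MC rat 3 (0.0599), and cholesterol synthesis when any of the 6 rats was left out (0.0860 to 0.266). Adipocytes were not called after quantile normalization without vehicle rat 1 (adjusted p = 0.0922). ER protein folding (-0.17), blood (-0.27), antioxidant genes (-0.15) and endometrial stroma (-0.14) were lower and cornified epithelium (0.12) higher on the deposited scale, with camera adjusted p of 0.00735, 0.0243, 0.0261, 0.0284 and 0.0206 (adjusted p = 0.929, 0.834, 0.929, 0.929 and 0.834 with an estimated correlation); after quantile normalization these 5 were not called. The 10 AhR target genes tested had a median of -0.07 (camera adjusted p = 0.641). Adipocyte markers differed between rats of the same group more than any other list, as the plot of list means per rat shows.

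Limma called 0 genes between 3-MC and vehicle, with 82 at an unadjusted p under 0.05 and a smallest adjusted p of 1.00. Quantile normalization also gave 0 (478 at an unadjusted p under 0.05), leaving out vehicle rat 2 gave 1, and weights estimated per array gave 4. With Cyp1a1, Cyp1b1 and Ahrr dim and no AhR target gene called, these marker genes do not show that the uteri were exposed to 3-MC when they were collected. Over all genes, 3.10% had 3-MC rats that did not overlap the vehicle rats, against 10% by chance. Of the 9 lists called, 2 stayed called without vehicle rat 1, 5 were lost, and the directions of cornified epithelium and stroma turned, with camera adjusted p of 0.788 and 0.561. Only 1 stayed called when quantile normalization was added. Without vehicle rat 1 on the deposited scale, 4 other lists were newly called. Macrophages were called there as well, in the direction opposite to that with all rats (camera adjusted p = 0.00916).

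The comparison of E2+3-MC with 3-MC asks how the uterus responds to estradiol when 3-MC is present. Here the median over all genes was 0.08 on the deposited scale and -0.03 after quantile normalization, so the values in this and the next paragraph are those after quantile normalization. Prss32 rose by 6.40, Cuzd1 by 5.95, Mmp7 by 5.71, Reg3g by 5.55 and Fam3d, which encodes a secreted cytokine-like protein, by 5.49. Them5 (-5.05), Gulo (-3.58), the Wnt inhibitor Wif1 (-3.34) and Cadps (-3.20) fell most. C3 rose by 5.30, S100g by 4.02 and Igf1 by 1.35, and Clu fell by 3.06. The E2 minus vehicle values above are on the deposited scale, where their median over all genes was -0.11 (-0.03 after quantile normalization). They should not be set beside the values here. After quantile normalization the E2 minus vehicle differences were 6.61 for C3, 4.81 for S100g, 1.16 for Igf1 and -3.35 for Clu. Pgr, called on the deposited scale (0.72 ± 0.22, adjusted p = 0.0494), was 0.31 higher and uncalled after quantile normalization (adjusted p = 0.127).

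Interferon, immune, epithelial and mitosis lists had members that rose with E2 in the presence of 3-MC. The medians here are after quantile normalization, and the counts and tests on the deposited scale. Of 29 interferon response genes, 23 rose (25 when adjusted over the list alone), with Mx1 at 2.75 and Ifit3 at 2.06 and a list median of 1.07 (camera adjusted p = 1.48e-17; adjusted p = 0.590 with an estimated correlation). Of 19 macrophage markers 12 rose (15 when adjusted over the list alone; median 0.96; camera adjusted p = 5.00e-09), of 19 antigen presentation genes 8 rose (16 alone; median 0.75; 4.12e-08) and of 29 epithelial genes 11 rose and 1 fell (16 and 2 alone; median 0.40; 1.36e-06), each with adjusted p = 0.590 with an estimated correlation. Of 23 mitosis genes 10 rose (13 when adjusted over the list alone), with Cdk1 at 2.43, Kif23 at 2.10 and the topoisomerase gene Top2a at 1.59 (camera adjusted p = 3.38e-07; adjusted p = 0.590 with an estimated correlation). Cholesterol synthesis (4 of 18 rose, Idi1 at 2.55) and ER protein folding (7 of 31 rose, P4hb at 0.93) both had a camera adjusted p of 1.85e-04 (adjusted p = 0.623 and 0.759 with an estimated correlation). The collagen genes Col1a1 and Col1a2 rose by 1.01 and 0.72 within the extracellular matrix list, in which 6 of 40 genes rose (camera adjusted p = 0.00274; adjusted p = 0.759 with an estimated correlation). Among antioxidant genes 7 of 26 rose and 1 fell (camera adjusted p = 0.0473, and 0.0747 after quantile normalization; adjusted p = 0.759 with an estimated correlation), with the glutathione synthesis gene Gclm at 1.30. Estrogen-induced genes (10 of 26 rose), complement (8 of 17 rose, 1 fell), chemokines (9 of 30 rose), neutrophils (3 of 6 rose) and DNA replication (3 of 29 rose) were higher relative to other genes, with camera adjusted p of 1.35e-08, 2.46e-05, 0.00169, 0.0143 and 0.0464 (adjusted p = 0.590, 0.590, 0.623, 0.590 and 0.759 with an estimated correlation). DNA replication was not called without E2+3-MC rat 1 (adjusted p = 0.385). Endothelium (median -0.49), mesothelium (-0.51), the Wnt pathway (-0.34) and steroid receptors (-0.28) were lower, with camera adjusted p of 5.66e-05, 0.0143, 5.36e-04 and 0.0450 (adjusted p = 0.590, 0.590, 0.666 and 0.759 with an estimated correlation). Steroid receptors were not called without 3-MC rat 1 (camera adjusted p = 0.0508), 3-MC rat 3 (0.0574) or E2+3-MC rat 1 (0.0570). Of the adipocyte markers Adipoq alone was called, 2.93 higher than with 3-MC.

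Limma called 834 genes between E2+3-MC and 3-MC, 693 higher and 141 lower, and 2647 after quantile normalization (1385 higher, 1262 lower). In 832 of the 834 genes the rats did not overlap, a share of 37.3% over all genes tested against 10% by chance. Without vehicle rat 1, which is in neither group but adds to the shared spread, the count was 2176; it was 413 without 3-MC rat 2, 495 without 3-MC rat 1, 489 without E2+3-MC rat 1, 442 without E2+3-MC rat 3 and 2270 with only the groups compared. The E2 responses without and with 3-MC share no array, and across the 10154 genes they correlated with Pearson r = 0.915 and Spearman rho = 0.846. In 100 simulations of unchanged groups r had a mean of 0.0569 and ranged from -0.805 to 0.775. Genes are not independent replicates. Of the called genes 601 were higher in both (60.3 from independent lists), 139 were lower in both (13.3 from independent lists), and 0 went in opposite directions, with 1 such gene after quantile normalization.

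**Figure D2:**
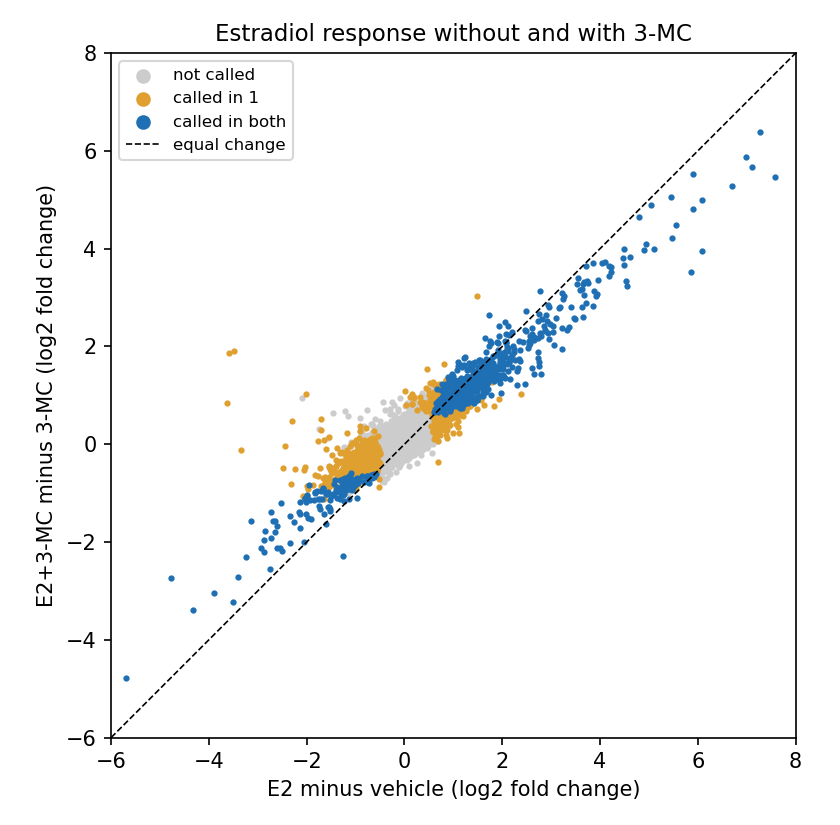
Log2 difference of E2 minus vehicle (horizontal) against E2+3-MC minus 3-MC (vertical) for 10154 genes, coloured by whether a gene was called in neither, in 1 or in both comparisons, with the line of equal change. Of the 601 genes higher in both, those with the largest rises lie mostly under the line.

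The comparison of E2+3-MC with vehicle gives the response to the combination. Cuzd1 rose by 6.71 ± 0.25, Mmp7 by 6.60 ± 0.28, C3 and Prss32 by 6.44 ± 0.26 each and Reg3g by 5.96 ± 0.60. The largest falls were in Them5 (-4.97 ± 0.29), Gulo (-3.69 ± 0.28), Wif1 (-3.34 ± 0.29) and Clu (-2.97 ± 0.23). Interferon response genes rose in 22 of 29 cases (camera adjusted p = 2.22e-18; adjusted p = 0.604 with an estimated correlation), with Mx1 up by 2.75. Mitosis genes rose in 10 of 23 cases (16 when adjusted over the list alone), with Cdk1 up by 2.31 and Kif23 by 2.23 (camera adjusted p = 2.56e-08; adjusted p = 0.604 with an estimated correlation). E2+3-MC rat 1 stood apart in this list, with a mean of 1.12 against 0.33 and 0.22 in rats 2 and 3. The vehicle rats had -0.12, -0.40 and -0.45. In the extracellular matrix list 5 of 40 genes rose and 2 fell, with the fibrillar collagen genes Col1a1 and Col1a2 up by 1.55 and 1.19 (camera adjusted p = 0.00293; adjusted p = 0.713 with an estimated correlation). Endothelial markers fell in 4 of 20 cases, with Flt1 at -0.82 and Tek at -0.79 (camera adjusted p = 7.36e-08; adjusted p = 0.604 with an estimated correlation).

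Other lists were also called against vehicle. Macrophages (8 of 19 rose), estrogen-induced genes (10 of 26 rose, 1 fell), antigen presentation (5 of 19 rose), complement (7 of 17 rose, 1 fell) and luminal and glandular epithelium (7 of 29 rose) were higher relative to other genes, with camera adjusted p of 7.36e-08, 7.71e-08, 8.50e-07, 5.48e-05 and 2.76e-04 (adjusted p = 0.604, 0.604, 0.604, 0.659 and 0.692 with an estimated correlation). Chemokines (8 of 30 rose, 1 fell), cholesterol synthesis (3 of 18 rose), DNA replication (3 of 29 rose), ER protein folding (2 of 31 rose) and neutrophils (2 of 6 rose) were higher at camera adjusted p of 9.52e-04, 0.00955, 0.00970, 0.0204 and 0.0452 (adjusted p = 0.684, 0.700, 0.700, 0.809 and 0.604 with an estimated correlation). The Wnt pathway (1 of 33 rose, 4 fell), blood (3 of 6 fell), steroid receptors (3 of 19 fell), peripheral nerve (1 of 8 fell, Gap43 at -1.20), mesothelium and adipocytes were lower at camera adjusted p of 3.01e-04, 0.00462, 0.00955, 0.0267, 0.0359 and 0.0452 (adjusted p = 0.692, 0.604, 0.700, 0.604, 0.684 and 0.718 with an estimated correlation). No member of the mesothelium or adipocyte list was called by limma. After quantile normalization adipocytes, mesothelium, neutrophils and peripheral nerve were not called (adjusted p = 0.398, 0.0661, 0.0784 and 0.0539), and without E2+3-MC rat 1 DNA replication and cholesterol synthesis were not (adjusted p = 0.173 and 0.0824). ER protein folding was lost without E2+3-MC rat 3 (0.308), vehicle rat 2 (0.125) or vehicle rat 3 (0.0519).

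Limma called 796 genes between E2+3-MC and vehicle, 615 higher and 181 lower, against 2647 after quantile normalization (1295 higher, 1352 lower) and 1069 after median centring (639 higher, 430 lower). The rats did not overlap in 755 of the called genes and in 17.9% of all genes (10% by chance). The count was 2699 without vehicle rat 1, 460 without E2+3-MC rat 1, 438 without E2+3-MC rat 3 and 296 with only the groups compared. Against the E2 minus vehicle differences, which share the vehicle arrays, r was 0.944 across genes, with a mean of 0.494 in 100 simulations of unchanged groups against the same vehicle arrays. These simulations ranged from -0.686 to 0.950, so r alone does not exceed what the shared arrays can give. The covariance was 0.361 against 0.0192 simulated. Higher in both were 555 genes (53.5 from independent lists) and lower in both 176 (17.1 from independent lists); part of the excess of these overlaps may come from the shared controls.

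The comparison of E2+3-MC with E2 asks what 3-MC adds to or takes from the estradiol response. The median over all genes was 0.15 on the deposited scale and -0.01 after quantile normalization, so the values here are those after quantile normalization. Periostin (Postn), an extracellular matrix protein gene that fell with E2, was called higher by 1.35 after quantile normalization (adjusted p = 0.00793) and missed the threshold on the deposited scale (1.49 ± 0.24, adjusted p = 0.0775). Dnajc14, a gene of the DnaJ co-chaperone family, was the only other gene called on that scale and was lower; on the deposited scale it differed by -0.96 (adjusted p = 0.132). The markers C3 (-0.22), S100g (0.03), Pgr (0.03) and Clu (0.28) were not called.

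Some gene lists were called with the preset correlation between genes. Cholesterol synthesis was lower with 3-MC (median -0.54 over 18 genes, with Msmo1 at -0.85 and Fdps at -0.78), as was luminal and glandular epithelium (median -0.30 over 29 genes, with Krt8 at -0.80 and Krt19 at -0.70). Their camera adjusted p was 7.23e-13 and 2.90e-10 on the deposited scale and 8.65e-10 and 3.38e-09 after quantile normalization (adjusted p = 0.950 with an estimated correlation on the deposited scale for each list in this paragraph). Estrogen-induced genes (median -0.23), ER protein folding (-0.14) and immediate early genes (-0.10) were lower as well, with camera adjusted p of 2.34e-06, 1.00e-05 and 0.00923, the last lost without E2+3-MC rat 1 (0.0846). E2+3-MC rat 2 stood apart in several of these lists: without it the deposited difference of list means went from -0.38 to -0.17 for cholesterol synthesis, from -0.21 to -0.08 for epithelium, from -0.17 to -0.02 for estrogen-induced genes and from -0.11 to 0.06 for ER protein folding. After quantile normalization these differences went from -0.50 to -0.33, -0.30 to -0.24, -0.27 to -0.18 and -0.18 to -0.08. For immediate early genes the deposited difference turned from -0.03 to 0.04 without that rat, and went from -0.17 to -0.15 after quantile normalization. Mitosis (median 0.30, Top2a at 0.83), DNA replication (0.16), mesothelium (0.38), adipocytes (0.78, Fabp4 at 2.86) and the Wnt pathway (0.06) were higher, with camera adjusted p of 2.08e-05, 5.75e-04, 5.77e-04, 0.00249 and 0.0423. E2+3-MC rat 1 stood apart in mitosis and DNA replication: its list means were 1.01 and 0.46, against 0.30 and 0.03 in rat 2 and 0.16 and 0.09 in rat 3, and without it neither list was called (adjusted p = 0.345 and 0.282). The adipocyte list was not called without E2+3-MC rat 2 (adjusted p = 0.313) or E2 rat 1 (0.471). Nor was the Wnt pathway without E2+3-MC rat 2 (0.354), E2 rat 1 (0.133) or E2 rat 2 (0.0879). Smooth muscle and macrophages were lower relative to other genes on the deposited scale only (camera adjusted p = 0.00306 and 0.0214; 0.153 and 0.510 after quantile normalization), and the macrophage median there was 0.04, opposite in sign to its test. Extracellular matrix, stroma and the insulin-like growth factor axis (medians 0.09, 0.14 and 0.16) were called higher and the EGF receptor axis (-0.23) lower after quantile normalization only, with camera adjusted p of 0.00139, 0.00687, 0.0120 and 0.0181 (adjusted p = 0.509, 0.570, 0.392 and 0.404 with an estimated correlation on that scale).

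Limma called 0 genes between E2+3-MC and E2 on the deposited scale, with 937 at an unadjusted p under 0.05. On that scale 17.9% of genes did not overlap (10% by chance). The log2 medians of the arrays did not overlap either, at 6.68 to 6.95 with E2 and 6.98 to 7.07 with E2+3-MC. This share therefore cannot be read as an effect of 3-MC apart from array scale. Counts under other settings were 2 after quantile normalization, 117 without vehicle rat 1, 18 without E2+3-MC rat 3, 1 without vehicle rat 3 or 3-MC rat 3, 144 with only the groups compared and 5128 with estimated array weights, which ranged from 0.0662 to 5.52. Of the 117, 18, 144 and 5128 genes, 109, 10, 124 and 4749 were higher, on the deposited scale where the median over all genes was 0.15. Quantile normalization without vehicle rat 1 called 19 genes, 7 higher and 12 lower. The larger counts thus cannot be told apart from a shift in array scale. The 3-MC differences without and with E2 share no array and had r = 0.147 and rho = 0.290 across genes, within the -0.764 to 0.808 of 100 simulations of unchanged groups.

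The interaction compares the E2 response with 3-MC to that without it. Its median over all genes was 0.19 on the deposited scale and -6.49e-04 after quantile normalization; the values here are those after quantile normalization. Adipocyte markers had the largest list median, 1.58 over 12 genes, with Fabp4 at 5.15 and Cidec at 2.50 (camera adjusted p = 7.55e-12 on the deposited scale; adjusted p = 0.774 with an estimated correlation). Vehicle rat 1 (list mean 1.73 against -0.10 and 0.33) and E2+3-MC rat 2 (1.10 against 0.02 and -0.37) stood apart in these genes, and the interaction of the list means was 1.81 with all rats and 0.85 without both. Cholesterol synthesis (median -0.37), estrogen-induced genes (-0.24, C3 at -1.31) and epithelium (-0.19) were lower (camera adjusted p = 1.84e-06, 3.21e-06 and 4.62e-04; adjusted p = 0.838, 0.838 and 0.876 with an estimated correlation). Without E2+3-MC rat 2 the interaction of the list means went from -0.32 to -0.15 for cholesterol synthesis. It went from -0.27 to -0.17 for estrogen-induced genes and from -0.18 to -0.12 for epithelium. On the deposited scale these values turned sign, from -0.19 to 0.02, from -0.14 to 0.01 and from -0.03 to 0.09. Without vehicle rat 1 they were -0.47, -0.41 and -0.31 on that scale, and without both rats -0.26, -0.26 and -0.19. Mitosis (0.34), DNA replication (0.16), stroma (0.19) and the insulin-like growth factor axis (0.15) were higher (camera adjusted p = 0.00461, 0.0266, 0.0173 and 0.0473; adjusted p = 0.876 with an estimated correlation for each). Without E2+3-MC rat 1 the mitosis list turned direction (adjusted p = 0.990) and DNA replication was not called (0.704); without vehicle rat 1, among others, stroma and the insulin-like growth factor axis were not called (0.375 and 0.0731). Limma called 0 genes for the interaction on the deposited scale (298 at an unadjusted p under 0.05, smallest adjusted p = 0.977) and 0 after quantile normalization (570, 0.360), and 1119 with estimated array weights. A difference between the E2 responses was thus not shown for any single gene on the deposited or the quantile-normalized values.

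**Figure D3:**
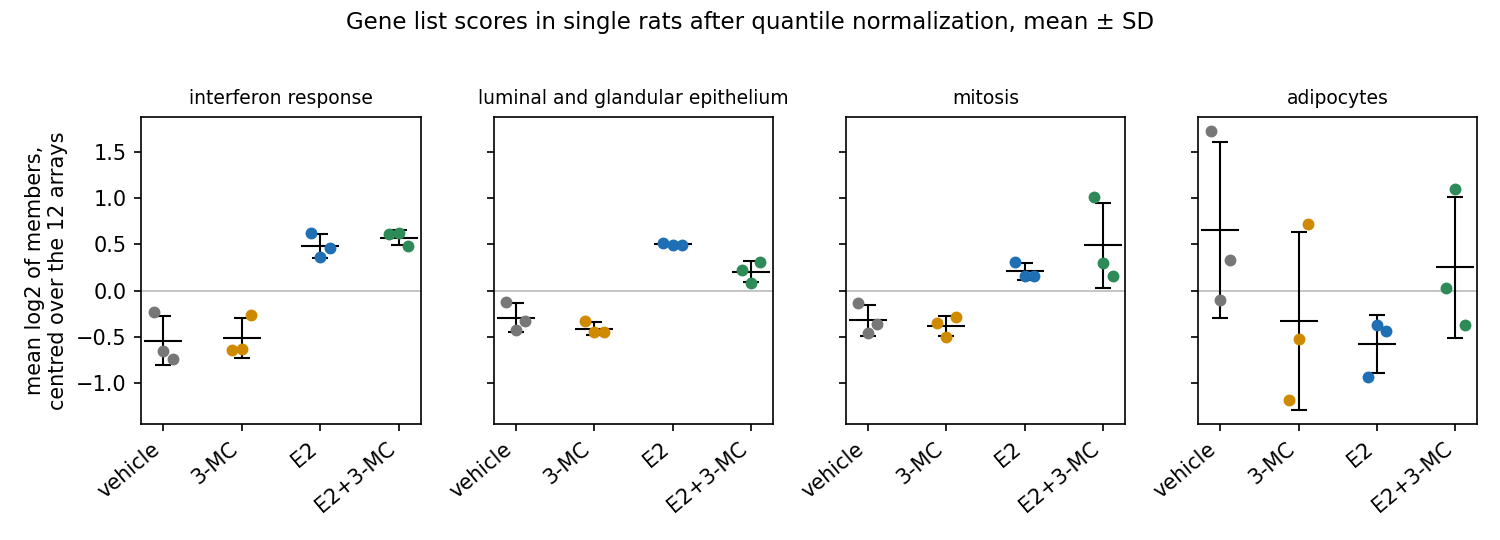
Mean log2 value of list members in each rat after quantile normalization, centred over the 12 arrays, for interferon response, luminal and glandular epithelium, mitosis and adipocyte genes in the 4 groups; bars give the mean and SD of 3 rats. Interferon, epithelium and mitosis genes lie higher in both groups given E2, while adipocyte genes spread within groups, from -1.18 to 0.72 among rats given 3-MC.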

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

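All tests of the patterns weighed here were chosen after the results were seen; the regroupings of arrays were fixed before the data were examined.

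C3, S100g, Mmp7 and Cuzd1, all strongly raised by E2, had higher mean levels with 3-MC than with vehicle, although none was called (adjusted p = 1.00), and C3, Mmp7 and Cuzd1 lay under the dim limit of 6.44 with vehicle (5.86, 5.34 and 5.40), which makes their differences and the shares below uncertain. The C3 intensity was 175 in 3-MC rat 3, 90.6 and 89.5 in the other rats given 3-MC, and 33.0 to 59.5 with vehicle. For S100g these values were 331, 179 and 199, and 106 to 143. In both genes 3-MC rat 3 adds most to the group means on which the shares rest. A trace of RNA from E2-treated uteri in the 3-MC samples would raise every strongly E2-raised gene by the same share. Of 18 other genes raised more than 16-fold, 16 lay below the rise at 0.665%, the smallest share that fits any of the 4 genes. The 4 genes had the largest 3-MC minus vehicle differences of all 22 (0.84 to 1.15, the next 0.62 for Scgb1a1). Lower values in the others thus follow in part from that choice. Only 1 of the 18, Prss32, lay more than 3 SE below the rise at 0.665%. That count cannot decide, since among the 18 only Prss32 (1.01, SE 0.26) had a predicted rise over 3 SE. For Fam3d the predicted rise was 0.47 (SE 0.24) and for Reg3g 1.11 (SE 0.60). The 4 genes do not give a common share (0.665% for Cuzd1, 0.682% for Mmp7, 1.27% for C3 and 2.88% for S100g, which lay 2.60 SE above the smallest), and a trace of such RNA stays open. A difference in the scale of the arrays could not be the whole cause, since the lowest of the 4 values was still 0.69 after quantile normalization. For an estradiol-like effect of 3-MC, the median of 121 other E2-raised genes was 0.0129, where the 0.665% share would give 0.06. Without vehicle rat 1 that median was 0.13 (after quantile normalization -0.04 with all rats and 0.06 without it). The deposited median over all genes moved likewise, from -0.05 to 0.15. A gap smaller than the move from leaving out that rat cannot decide, so an estradiol-like effect, on few or many genes, also stays open. So does chance, since the 4 genes were picked from these data by their size. Of 10154 genes only 82 had an unadjusted limma p under 0.05, and 3.10% did not overlap, against 10% by chance.

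In 136 of 149 genes strongly responding to E2, the E2+3-MC minus E2 difference opposed the E2 response, with a median loss of -0.51. This loss compares levels with E2 present. The interaction, which compares the E2 responses without and with 3-MC, had a median of -0.54 in the direction of the response. Without E2+3-MC rat 2, 116 of the 149 genes showed a loss. Array scale is argued against as the cause, because the loss was -0.52 after quantile normalization. A single rat could carry much of it: without E2+3-MC rat 2 the loss was -0.17, or -0.27 after quantile normalization. An effect of 3-MC itself remains possible, with an exact permutation p of 0.1 on the quantile-normalized scores, the smallest that 3 against 3 rats allow, and 0.3 on the deposited ones. Rats of the E2 group scored 1.68 to 1.94 and those of the E2+3-MC group 1.34, 0.68 and 1.84.

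Adipocyte markers differed between rats given the same treatment. The within-group SD of their score was 0.793 after quantile normalization, the highest of 35 lists, with a mean correlation of 0.789 between members, values that describe the pattern and do not decide whether fat attached to single uteri could be its source. E2 treatment might add to it: the E2 minus vehicle median of the list was -1.55 with all rats and -0.80 without vehicle rat 1 (-1.27 and -0.77 after quantile normalization). In each of these 4 cases the scores of all E2 rats lay below those of all vehicle rats. The exact permutation p was 0.1, the smallest that these numbers of rats allow. Adipoq, an adipocyte hormone gene, was 1.49 ± 0.73 higher with E2 (adjusted p = 0.174) while Fabp4 and Lpl fell, so the members did not share 1 direction. Attached fat and E2 treatment do not exclude each other, and whether 1 or both hold stays open.

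Other results that stood apart are given by value. The interaction medians of the called lists on the deposited scale were 1.77 for adipocytes, 0.51 for mesothelium, 0.49 for mitosis, 0.37 for endometrial stroma, 0.37 for the insulin-like growth factor axis, 0.34 for DNA replication, 0.32 for the Wnt pathway, 0.32 for endothelium, 0.0858 for cornified epithelium and 0.0140 for the EGF receptor axis. They were -0.26 for cholesterol synthesis, -0.22 for skeletal muscle, -0.10 for estrogen-induced genes and -0.0327 for luminal and glandular epithelium. Camera placed cornified epithelium and the EGF receptor axis lower than other genes despite their positive medians, at adjusted p = 0.0473 each (adjusted p = 0.838 and 0.876 with an estimated correlation). With an estimated correlation all 14 lists had an adjusted p of 0.774 to 0.876, and after quantile normalization mesothelium, the Wnt pathway, endothelium, skeletal muscle, cornified epithelium and the EGF receptor axis were not called (0.0786, 0.0786, 0.171, 0.163, 0.196 and 0.0786). Of 13581 probe sets with no listed gene 8509 were tested, and 374 were called higher and 661 lower in E2 than in vehicle.

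Regrouping the 6 arrays of a comparison in all 10 ways gives too few splits for a share under 0.05. For E2 minus vehicle 1 of 10 splits called as many genes as the real one (1842, highest other 0), and for E2+3-MC minus 3-MC 1 of 10 (834, highest other 0). For 3-MC minus vehicle and E2+3-MC minus E2, where limma called 0 genes, 10 of 10 did, which a real count of 0 makes certain, so the check cannot decide there. For E2+3-MC minus vehicle 2 of 10 did: the real split gave 796 and vehicle rat 1 with E2+3-MC rats 1 and 3 against the rest gave 2020, where after quantile normalization the real split gave 2647 and the highest other 1. For the interaction the real count was 0 as well, so all 100 groupings, the real one among them, had to reach it. The check cannot decide there either, and the highest other count was 3.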

How the results depend on the processing

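The tests that combine quantile normalization with the replicate block or with rats left out were chosen after seeing the data; the others were fixed before the data were examined.

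The counts moved with single arrays, vehicle rat 1 among them, with the scale of the arrays and with array weights. Of the comparisons with a count of 0, E2+3-MC minus E2 moved in each of these ways. In the others 3-MC minus vehicle reached at most 4, and the interaction moved with array weights only. The counts in limma were 1842 for E2 minus vehicle, 0 for 3-MC minus vehicle, 796 for E2+3-MC minus vehicle, 0 for E2+3-MC minus E2, 834 for E2+3-MC minus 3-MC and 0 for the interaction. Quantile normalization gave 3901, 0, 2647, 2, 2647 and 0 in the same order, and median centring called 1 gene between E2+3-MC and E2. Leaving out the lowest 50% gave 1183 for E2 minus vehicle and 1 for E2+3-MC minus E2, and every probe set gave 3011 and 1. Only the groups compared gave 961 for E2 minus vehicle, 296 for E2+3-MC minus vehicle, 144 for E2+3-MC minus E2 and 2270 for E2+3-MC minus 3-MC. Trend and robust fitting called 3 genes between E2+3-MC and E2. Array weights gave 6197, 4, 4563, 5128, 3931 and 1119 for the 6 comparisons in that order. At least 2-fold left 851, 519 and 550 genes and an adjusted p under 0.01 left 934, 429 and 439, for E2 minus vehicle, E2+3-MC minus vehicle and E2+3-MC minus 3-MC. The cause was not tested.

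Rats left out in turn gave 986 to 3541 genes for E2 minus vehicle, 0 to 1 for 3-MC minus vehicle, 438 to 2699 for E2+3-MC minus vehicle, 0 to 117 for E2+3-MC minus E2, 413 to 2176 for E2+3-MC minus 3-MC and 0 to 0 for the interaction. Without vehicle rat 1 the counts were 3541 for E2 minus vehicle, 2699 for E2+3-MC minus vehicle, 117 for E2+3-MC minus E2 and 2176 for E2+3-MC minus 3-MC. E2 minus vehicle gave 1151 without E2 rat 2 and 986 without E2 rat 3. E2+3-MC minus vehicle gave 460 without E2+3-MC rat 1 and 438 without E2+3-MC rat 3. E2+3-MC minus 3-MC gave 495 without 3-MC rat 1, 413 without 3-MC rat 2, 489 without E2+3-MC rat 1 and 442 without E2+3-MC rat 3. E2+3-MC minus E2 gave 18 without E2+3-MC rat 3 and 1 without vehicle rat 3 or 3-MC rat 3, and 3-MC minus vehicle gave 1 without vehicle rat 2.

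The replicate numbers were checked for pairing. The 18 pairs of arrays with the same number correlated at -0.27 to 0.24 after removal of group means, and 2 of 12 arrays correlated best with an array of their own number, with 8 of the 18 pairs over 0.1, among them all 3 pairs of E2 and 3-MC (0.239, 0.159 and 0.170). Since not every pair was over 0.1, the numbers were not treated as pairing rats. With the replicate block the counts were 2545, 0, 1089, 0, 1140 and 0 in the order used above. All 128, 97 and 101 named genes called for E2 minus vehicle, E2+3-MC minus vehicle and E2+3-MC minus 3-MC stayed called with the block. Of the called lists 15 of 16, 9 of 9, 19 of 20, 11 of 12, 18 of 18 and 11 of 14 stayed called: blood was not called for E2 minus vehicle (adjusted p = 0.0620), adipocytes for E2+3-MC minus vehicle (0.0666), the Wnt pathway for E2+3-MC minus E2 (0.0645), nor cornified epithelium, endothelium and the insulin-like growth factor axis for the interaction (0.0576, 0.0657 and 0.0625). Quantile normalization with the block gave 3815, 0, 2540, 3, 2555 and 0. Quantile normalization without vehicle rat 1 gave 4677, 0, 3336, 19, 3454 and 0, without E2+3-MC rat 2 gave 4009, 0, 2624, 1, 2654 and 0, and without both gave 4981, 0, 3699, 4, 3718 and 0.

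Of the named genes called, 99 to 128 of 128 stayed called over the 25 settings for E2 minus vehicle, 51 to 97 of 97 for E2+3-MC minus vehicle and 66 to 101 of 101 for E2+3-MC minus 3-MC, and 0 named genes reversed. The correlation between 3-MC minus vehicle and E2+3-MC minus E2 was 0.147 by Pearson and 0.290 by Spearman. With an estimated correlation camera kept 0 of the 16, 9, 20, 12, 18 and 14 lists called in the 6 comparisons, and quantile normalization kept 14, 4, 16, 10, 17 and 8.

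Some lists reversed. Fry put the EGF receptor axis upward in the interaction (adjusted p = 0.997), and mitosis turned without E2+3-MC replicate 1 in the interaction (0.990; 3.81e-07 without E2+3-MC rat 3). For 3-MC minus vehicle without vehicle replicate 1, cornified epithelium turned downward (0.788), endometrial stroma upward (0.561), and macrophages turned too (0.00916). Macrophages were not among the 9 lists called with all rats, and were called in the turned direction. With single rats left out, the camera adjusted p of cornified epithelium ran from 0.00779 (without vehicle rat 2) to 0.788. For stroma it ran from 0.00339 (without vehicle rat 3) to 0.561. For macrophages it ran from 1.06e-04 (without 3-MC rat 3) to 0.634 (without 3-MC rat 2). Each range takes in the turned fit without vehicle rat 1. After quantile normalization without vehicle rat 1 the same 3 lists had 0.979, 0.698 and 0.0365, and without both rats 0.983, 0.692 and 0.0410. The adipocyte list for E2+3-MC minus vehicle turned after quantile normalization without vehicle rat 1 (0.807). The cause was not tested.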

Other observations

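The values below were picked after the results were seen, and no further tests were chosen for them.

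E2 also changed single genes of ion transport, steroid handling and cytokine signalling. Cftr, a chloride channel, rose by 4.49 and Hsd11b2, which inactivates glucocorticoids, rose by 3.16 with E2, while Nr3c2, the mineralocorticoid receptor that this enzyme protects from glucocorticoids, fell by 1.28. Il1rn, which blocks the interleukin-1 receptor, rose by 2.95 beside the chemokines. Sgk1, a kinase that controls sodium channels, rose by 1.00.

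Igfbp3, a carrier that holds insulin-like growth factors in the circulation, fell by 1.40 and the stanniocalcin gene Stc1 fell by 1.75, while Igf1 and Igfbp2 rose with E2. Frzb, a secreted Wnt inhibitor, rose by 1.11 from vehicle to E2+3-MC, while the inhibitor Wif1 fell by 3.34.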
